A study of Mus musculus with 4 samples.

How the data were processed

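Poly(A)-selected RNA of ILC2s sorted from mouse lung was sequenced in 4 libraries, 2 per group, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was treated with DNase I, selected with oligo(dT) beads, fragmented and amplified by PCR. The deposited table holds whole-number read counts per Entrez gene, with 1 column for each library and no normalization. Per the submitters' processing notes, fastp, HISAT2 2.2.1, featureCounts 2.0.1 and edgeR 3.34.0 were used with the mm10 build, without stated roles or settings. Strandedness and the treatment of reads that map to several places are not given in the sources used here. Reads shared by close paralogs (such as Chil3 and Chil4, the hemoglobin alpha genes, Bcl2a1b and Bcl2a1d, or the Ly6, H2, Oas and Gbp families), by overlapping genes or by antisense partners can therefore be assigned to the wrong gene, and such levels are uncertain.

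The table has 27179 gene identifiers. Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, which matched 25275 of them, and the 1904 unmatched identifiers held from 0.519 to 0.641% of the counts of a library. All counts were zero for 9144 identifiers. Every value column was mapped to a library by its name. Library totals ran from 14027720 to 16420948 counts, and intervals given for counts cover counting error only. Replicates were compared before they were averaged: chi-square divided by degrees of freedom was 14.1 for the PBS pair and 26.8 for the papain pair, so neither pair was 1 library deposited again. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.98 within PBS, 0.97 within papain and 0.94 to 0.95 between groups, and the first principal component, with 66.2% of the variance, separated the groups while the next, with 22.8%, put both libraries numbered 1 on one side and both numbered 2 on the other.

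Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM normalization, glmQLFit and glmQLFTest, group as the only term, 2 residual degrees of freedom). All tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and the common biological coefficient of variation was 0.168. A shortfall from this threshold does not show that a gene did not differ. TMM factors ran from 0.951 to 1.05, and the CPM printed are divided by the normalized library size. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 10 and no overlap between groups, leaving out predicted gene models and antigen receptor segments, up to 4 members of each list with the smallest adjusted p, a set of ILC2 genes (Smarca4, Il4, Il5, Il13, Il9, Csf2, Areg, Gata3, Il1rl1, Il2ra, Klrg1, Mki67, Arg1, Tcf7, Il17rb and Icos) and the most abundant member of each marker list. Members of a list given by name because 5 or fewer of them moved (such as Cdt1, Cks2 and Pttg1), and the genes named in the additional observations, were chosen after their values were seen.

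The 23 functional lists and the marker and quality lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted within each of the 2 kinds of list, where at least 5 members were measured. NK cell and ILC1, neutrophil, eosinophil and mitochondrial lists had fewer measured members and were not tested. Ratios of low counts carry an exact 95% interval.

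The alternatives were DESeq2 1.42.0, limma-voom and the edgeR exact test, RLE and upper quartile normalization and scaling by library size only, no filter and a filter on a mean CPM of at least 5, the replicate number as a block, a robust fit, each library left out in turn, glmTreat against 2-fold, an adjusted p under 0.01, and for lists an estimated correlation, fry and ranks. With 1 library left out, the lone library of its group is assumed to vary like the other group. Without a PBS library the spread therefore comes from the papain pair alone, which differed more than the PBS pair. A call lost there need not mean that the effect rested on the left-out library. List tests were not repeated under DESeq2, the exact test and the robust fit, since camera works on log2 CPM and takes nothing from those gene tests. Alternatives set for normalized values did not apply to counts. In simulated data for papain against PBS (12411 genes tested), 51% of 2-fold and 82% of 4-fold changes were recovered, 99% with the right sign. There 14 unchanged genes were called, 9.5% of the calls. With nothing changed, 2 genes and 0 of 23 lists were called, and with glycolysis raised 1.5-fold, 1 list. Neither run tests list calls among correlated genes. Trends over transcript length and GC content were fitted with mgcv 1.9.3, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.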

Results

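Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes without rearranged antigen receptors that secrete type 2 cytokines. They were sorted by flow cytometry from the lungs of wild-type female mice as lineage-negative cells carrying CD25, the interleukin-2 receptor alpha chain, and ST2, the interleukin-33 receptor. Of the 4 RNA-seq libraries, 2 came from mice given phosphate-buffered saline (PBS) and 2 from mice given papain, a plant cysteine protease used as an airway allergen. The papain dose is stated in conflicting ways, as 30 ng in the titles, 30 µg in the treatment labels and 50 µg per day for 3 days in the protocol. Libraries held 14027720 and 15348321 counts for PBS and 15801673 and 16420948 counts for papain. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The series is about the control of ILC2s by Brg1, the SWI/SNF ATPase encoded by Smarca4. Its single comparison asks which transcripts differ between resting and papain-exposed cells.

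After papain, lung ILC2s held more RNA of many cell-cycle, interferon-stimulated and secretory genes, of genes of some metabolic lists and of several type 2 cytokines, and less of many immediate early genes. These list calls rest on a preset correlation. The estimate of a correlation had 2 residual degrees of freedom and so little power, and its lack of calls does not decide whether a list changed. Unlike the preset correlation, the estimated one called 0 of 23 lists (lowest adjusted p = 0.373, with an unadjusted camera p of 0.0242 for G2/M and mitosis). Glycolysis and arginine and polyamine genes were not called as lists with either (adjusted p = 0.0921 and 0.262 with the preset correlation, with alternatives from 0.0228 to 0.528 and from 0.0585 to 0.481, the lowest for glycolysis being without PBS replicate 1). Mki67, a marker of proliferating cells, rose from 12.6 ± 1.12 to 243 ± 4.52 CPM (log2 fold change 4.27, SE 0.15, adjusted p = 2e-05). Il13, which encodes a type 2 effector cytokine, rose from 50.8 ± 11.2 to 312 ± 9.60 CPM (log2 fold change 2.62, SE 0.18, adjusted p = 0.000166). Fosb, which encodes an AP-1 subunit, fell from 14392 ± 766 to 5299 ± 854 CPM (log2 fold change -1.44, SE 0.18, adjusted p = 0.00178). Values are means of normalized CPM ± SD over n = 2 libraries per group, and gene p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 12666 genes tested, 2590 changed, 1492 upward and 1098 downward. Changes of at least 2-fold were called for 958 genes, 662 upward and 296 downward. The papain libraries lay wholly above or below the PBS libraries in 63.6% of tested genes, against 33.3% by chance. Without PBS replicate 1, 293 genes changed (229 upward, 64 downward), and without PBS replicate 2, 391 (274 upward, 117 downward). Without papain replicate 1, 2273 changed (1314 upward, 959 downward), and without papain replicate 2, 3123 (1648 upward, 1475 downward). In that order, 292, 383, 914 and 1367 genes changed at least 2-fold. Scaling by library size only gave 1905 genes higher and 855 lower, or 69% higher against 57.6%.

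The largest rises among well-expressed genes were in cell-cycle genes together with Col18a1, Il1r2 and Chil3. E2f2, a cell-cycle transcription factor, rose from 0.315 ± 0.0206 to 20.6 ± 0.0492 CPM (log2 fold change 5.99, SE 0.30, adjusted p = 5.11e-05). Il1r2, the decoy receptor for interleukin-1, rose from 1.53 ± 1.10 to 70.6 ± 15.9 CPM (log2 fold change 5.49, SE 0.36, adjusted p = 0.000166). Col18a1, the collagen XVIII chain, rose from 0.892 ± 0.330 to 38.6 ± 4.67 CPM (log2 fold change 5.44, SE 0.27, adjusted p = 5.11e-05). Chil3, a chitinase-like protein of lung macrophages, stood at 97.0 and 35.7 CPM in the papain libraries. Its PBS mean was 2.01 ± 0.409 CPM (log2 fold change 5.03, SE 0.51, adjusted p = 0.00077). Pclaf, Clspn, Ccna2, Ccnb2 and Stmn1 rose with log2 fold changes of 4.84, 4.30, 4.22, 4.17 and 4.15. Mapk12, the p38 gamma kinase, fell from 76.4 ± 4.52 to 13.3 ± 0.364 CPM (log2 fold change -2.52, SE 0.14, adjusted p = 0.000102). Zbtb16, the transcription factor PLZF of innate-like lymphocytes, fell from 24.4 ± 6.46 to 6.67 ± 0.907 CPM (log2 fold change -1.87, SE 0.24, adjusted p = 0.0022). Cd24a, Abca1, Pou6f1, Fbxl21 and the pseudogene Slfn10-ps fell with log2 fold changes of -1.89, -1.88, -2.11, -2.28 and -1.98. Igf2 and Neo1 fell with -2.17 and -2.03. Igf2 lost its call with either PBS replicate left out (log2 fold changes -2.965 to -1.664 over left-out libraries). Neo1 lost its call with either PBS replicate left out (log2 fold changes -3.156 to -1.399 over left-out libraries). Chil3 and Slfn10-ps have close paralogs among which reads can be divided, so their levels are uncertain.

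Positions of the main genes are on GRCm38 (mm10). They are Il13 (Entrez gene 16163) on chromosome 11 from 53631323 to 53634702, Mki67 (Entrez gene 17345) on chromosome 7 from 135689784 to 135716450 and Ctla4 (Entrez gene 12477) on chromosome 1 from 60909025 to 60915832. Others are Irf4 (Entrez gene 16364) on chromosome 13 from 30749233 to 30766981, Col18a1 (Entrez gene 12822) on chromosome 10 from 77052178 to 77166530 and Il1r2 (Entrez gene 16178) on chromosome 1 from 40084692 to 40125230. Further rising genes are E2f2 (Entrez gene 242705) on chromosome 4 from 136172274 to 136196057 and Chil3 (Entrez gene 12655) on chromosome 3 from 106147554 to 106167564. Among falling genes are Mapk12 (Entrez gene 29857) on chromosome 15 from 89130584 to 89141577, Fosb (Entrez gene 14282) on chromosome 7 from 19302696 to 19310118 and Zbtb16 (Entrez gene 235320) on chromosome 9 from 48651797 to 48836225. The gene of Brg1 is Smarca4 (Entrez gene 20586) on chromosome 9 from 21616106 to 21704230. All are annotated as protein-coding, and each value is the sum over a gene, so exons, introns and untranslated regions are not told apart.

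**Figure D1:**
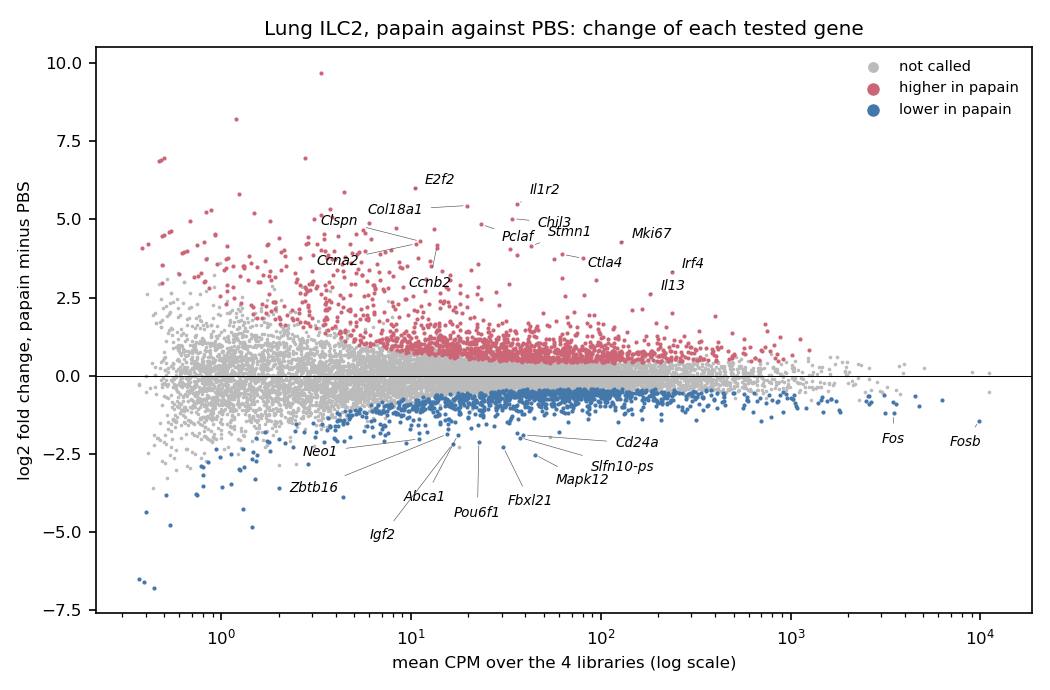
Each point is 1 of the 12666 tested genes, with mean CPM over the 4 libraries on a log scale on the x axis and the log2 fold change (papain minus PBS) on the y axis. The 1492 genes called higher in papain are red, the 1098 called lower are blue, the others are grey, and named genes are labelled, with Mki67 at 4.27 and Mapk12 at -2.52.

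Type 2 effector genes changed unevenly, with 10 of 24 called higher, and their call as a list was lost with an estimated correlation. Il13 rose as given above. Csf2, which encodes the growth factor GM-CSF, rose from 266 ± 6.62 to 566 ± 38.8 CPM (log2 fold change 1.09, SE 0.14, adjusted p = 0.00227). Csf2 lost its call with either PBS replicate left out (log2 fold changes 1.006 to 1.161 over left-out libraries). Areg, which encodes the repair factor amphiregulin, rose from 546 ± 9.01 to 1084 ± 22.3 CPM (log2 fold change 0.99, SE 0.14, adjusted p = 0.00328). Areg lost its call with either PBS replicate left out (log2 fold changes 0.959 to 1.003 over left-out libraries). Il4, a cytokine at a low level here, rose from 6.21 ± 2.36 to 13.2 ± 2.88 CPM (log2 fold change 1.10, SE 0.30, adjusted p = 0.0374). Il4 lost its call without PBS replicate 1 (adjusted p = 0.0826), without PBS replicate 2 (adjusted p = 0.231) and without papain replicate 1 (adjusted p = 0.103), with 0.000438 to 0.231 over the alternatives. Il5, the eosinophil growth factor gene, did not pass the test, at 607 ± 299 CPM in PBS and 975 ± 199 CPM in papain (log2 fold change 0.68, SE 0.31, adjusted p = 0.152). Il5 was called with no filter (adjusted p = 0.000791) and with a replicate-number term (adjusted p = 0.0195), with 0.000791 to 0.603 over the alternatives. The neuropeptide precursor Penk and the chemokine Cxcl3 rose with log2 fold changes of 3.91 and 2.54. Tnf, an inflammatory cytokine, fell from 187 ± 2.99 to 81.8 ± 7.53 CPM (log2 fold change -1.19, SE 0.13, adjusted p = 0.00124). Il9 held 2 counts over both PBS libraries and 59 over both papain libraries, a ratio of 25.4 (95% counting interval 6.72 to 214, adjusted p = 0.0262). Il9 lost its call without PBS replicate 1 (adjusted p = 0.123), without PBS replicate 2 (adjusted p = 0.211) and without papain replicate 1 (adjusted p = 0.104), with 0.000337 to 0.211 over the alternatives. Of 24 measured type 2 cytokine and effector genes, 10 rose, 2 fell and 12 did not pass the test, against 11 up and 4 down adjusted over the list alone. Rises of type 2 cytokine and effector genes numbered 3, 3, 7 and 14 and falls 1, 2, 3 and 3 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For type 2 cytokine and effector genes the median log2 fold change was 0.62 (camera adjusted p = 0.0194, from 0.000547 to 0.481 over the alternatives, and adjusted p = 0.481 with an estimated correlation). The type 2 cytokine and effector list lost its call without papain replicate 1 (adjusted p = 0.0507) and with fry (adjusted p = 0.102). The falling type 2 cytokine and effector genes were Tnf and Il2.

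**Figure D2:**
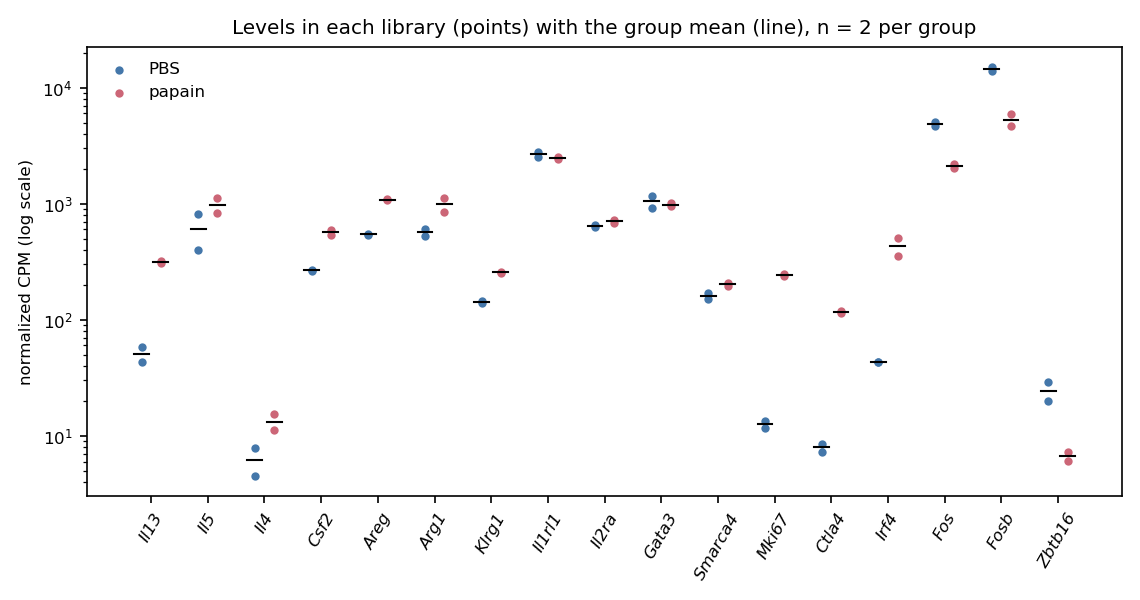
Points are normalized CPM on a log scale (y axis) in each PBS (blue) and papain (red) library for 17 genes (x axis), and black lines are group means. The Il13 libraries lie at 58.7 and 42.9 CPM for PBS and 305 and 319 CPM for papain.

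Genes of the dividing cell had the highest medians of the 23 lists. Ccnb2, the mitotic cyclin B2, rose from 1.43 ± 0.216 to 26.0 ± 4.05 CPM (log2 fold change 4.17, SE 0.25, adjusted p = 0.000147). Kif11, a mitotic motor, rose from 3.50 ± 0.174 to 41.5 ± 10.9 CPM (log2 fold change 3.56, SE 0.24, adjusted p = 0.000166). Of 40 measured G2/M and mitosis genes, 34 rose, 2 fell and 4 did not pass the test, against 36 up and 2 down adjusted over the list alone. Rises of G2/M and mitosis genes numbered 23, 26, 36 and 33 and falls 0, 0, 1 and 2 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For G2/M and mitosis genes the median log2 fold change was 3.23 (camera adjusted p = 7.37e-20, from 2.87e-24 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The falling G2/M and mitosis genes were Cks2 and Pttg1. Uhrf1, which maintains DNA methylation at replication forks, rose from 4.64 ± 0.515 to 67.3 ± 3.49 CPM (log2 fold change 3.85, SE 0.17, adjusted p = 3.48e-05). Mcm6, a subunit of the replicative helicase, rose from 35.6 ± 4.21 to 137 ± 1.01 CPM (log2 fold change 1.95, SE 0.14, adjusted p = 0.000223). Of 40 measured DNA replication and S phase genes, 31 rose, 1 fell and 8 did not pass the test, against 33 up and 1 down adjusted over the list alone. Rises of DNA replication and S phase genes numbered 18, 21, 28 and 29 and falls 0, 0, 0 and 1 with 1 library left out, in the same order. For DNA replication and S phase genes the median log2 fold change was 1.40 (camera adjusted p = 2.67e-15, from 3.75e-18 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The falling DNA replication and S phase gene was Cdt1. Beside these lists, markers of macrophages and monocytes summed to 41.5 and 44.6 CPM in PBS and 216 and 101 CPM in papain.

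Interferon-stimulated genes, which cells express in response to interferons, were called higher as a list with the preset correlation. Mx1, annotated as a transcribed pseudogene in the gene table used, rose from 0.216 ± 0.119 to 7.48 ± 3.51 CPM (log2 fold change 5.09, SE 0.61, adjusted p = 0.00165). Ifi27l2a, an interferon-induced protein, rose from 0.455 ± 0.00767 to 11.0 ± 5.69 CPM (log2 fold change 4.56, SE 0.51, adjusted p = 0.0012). Oas3, a sensor of double-stranded RNA, rose from 10.8 ± 0.00222 to 36.9 ± 2.37 CPM (log2 fold change 1.77, SE 0.16, adjusted p = 0.00054). Zbp1, a sensor of nucleic acids, rose with a log2 fold change of 1.47. Of 40 measured interferon-stimulated genes, 25 rose, 0 fell and 15 did not pass the test, against 29 up and 0 down adjusted over the list alone. Rises of interferon-stimulated genes numbered 4, 6, 22 and 25 and falls 0, 0, 0 and 1 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For interferon-stimulated genes the median log2 fold change was 1.11 (camera adjusted p = 1.41e-11, from 8.47e-14 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). Beside this list, the sum of the macrophage and monocyte markers stood at 41.5 and 44.6 CPM in the PBS libraries and 216 and 101 CPM in the papain libraries, with 4 of 8 members called higher (2 without papain replicate 1) and a camera adjusted p of 0.261. In the papain libraries Mx1 had 165 and 83 counts and Ifi27l2a stood at 15.0 and 6.93 CPM, whereas Oas3 stood at 38.5 and 35.2 CPM and Zbp1 at 46.3 and 51.6 CPM. The Oas and Gbp genes lie in clusters of similar genes among which reads can be divided.

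Several receptors of activated lymphocytes rose, but co-stimulatory and inhibitory receptors and ILC2 lineage genes each went both ways as lists. Ctla4, an inhibitory receptor, rose from 7.93 ± 0.878 to 117 ± 2.48 CPM (log2 fold change 3.89, SE 0.16, adjusted p = 2.42e-05). Havcr2, which encodes TIM-3, rose from 3.68 ± 0.735 to 37.9 ± 3.69 CPM (log2 fold change 3.37, SE 0.21, adjusted p = 0.000166). Tnfrsf4, which encodes OX40, rose from 6.77 ± 0.921 to 27.7 ± 0.859 CPM (log2 fold change 2.03, SE 0.19, adjusted p = 0.000574). Of 29 measured co-stimulatory and inhibitory receptor genes, 11 rose, 5 fell and 13 did not pass the test, against 11 up and 5 down adjusted over the list alone. Rises of co-stimulatory and inhibitory receptor genes numbered 6, 6, 10 and 11 and falls 0, 0, 4 and 2 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For co-stimulatory and inhibitory receptor genes the median log2 fold change was 0.09 (camera adjusted p = 0.0633, from 0.0167 to 0.53 over the alternatives). The co-stimulatory and inhibitory receptor list was called with limma-voom (adjusted p = 0.0475), with no filter (adjusted p = 0.0232) and without PBS replicate 1 (adjusted p = 0.0167). Its falling genes were Vsir, Cd200r1, Cd27, Tnfrsf18 and Socs2, which encodes no receptor. The mean log2 fold change of the whole list was 0.74. Beside the rising receptors, the summed regulatory T cell markers, which include Ctla4, stood at 359 and 362 CPM in PBS and 874 and 816 CPM in papain. Itgae, the integrin CD103, rose from 3.83 ± 1.79 to 62.6 ± 4.45 CPM (log2 fold change 4.04, SE 0.27, adjusted p = 0.000166). Ly6a, which encodes Sca-1 and has close paralogs, rose with a log2 fold change of 2.13, whereas Zbtb16 fell. Klrg1, a receptor of inflammatory ILC2s, rose from 142 ± 3.09 to 256 ± 4.37 CPM (log2 fold change 0.86, SE 0.13, adjusted p = 0.00415). Klrg1 lost its call with either PBS replicate left out (log2 fold changes 0.822 to 0.877 over left-out libraries). Of 29 measured ILC2 lineage genes, 6 rose, 5 fell and 18 did not pass the test, against 7 up and 5 down adjusted over the list alone. Rises of ILC2 lineage genes numbered 3, 2, 5 and 7 and falls 1, 1, 3 and 7 with 1 library left out, in the same order. For ILC2 lineage genes the median log2 fold change was -0.11 (camera adjusted p = 0.899, from 0.341 to 0.949 over the alternatives). The falling ILC2 lineage genes were Zbtb16, Lmo4, Kit, Ptpn13 and Il7r. The mean of the whole lineage list was 0.09 and the camera test pointed down, while the fry test pointed up.

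Neither the lineage regulator Gata3 nor the sort markers passed the test. Gata3 stood at 1045 ± 184 CPM in PBS and 982 ± 37.3 CPM in papain (log2 fold change -0.09, SE 0.17, adjusted p = 0.739). Il1rl1, which encodes ST2, stood at 2671 ± 180.4 CPM in PBS and 2476 ± 91.5 CPM in papain (log2 fold change -0.11, SE 0.15, adjusted p = 0.644). Il2ra, which encodes CD25, stood at 643 ± 16.5 CPM in PBS and 707 ± 26.7 CPM in papain (log2 fold change 0.14, SE 0.14, adjusted p = 0.529). Cells were sorted on the last 2 proteins, so their RNA levels are not counted as findings. Icos, Il17rb and Tcf7 did not pass the test either, with log2 fold changes of -0.21, 0.07 and -0.37. Ltb4r1, a receptor for leukotriene B4, rose from 75.0 ± 5.39 to 199.6 ± 12.2 CPM (log2 fold change 1.41, SE 0.14, adjusted p = 0.000622). Ptgir, the prostacyclin receptor, fell from 254 ± 13.9 to 140.4 ± 7.50 CPM (log2 fold change -0.86, SE 0.13, adjusted p = 0.00479). Ptgir lost its call with either PBS replicate left out (log2 fold changes -0.914 to -0.813 over left-out libraries). Of 30 measured alarmin, cytokine, lipid mediator and neuropeptide receptor genes, 5 rose, 7 fell and 18 did not pass the test, against 6 up and 7 down adjusted over the list alone. Rises of alarmin, cytokine, lipid mediator and neuropeptide receptor genes numbered 2, 1, 3 and 5 and falls 0, 0, 7 and 4 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For alarmin, cytokine, lipid mediator and neuropeptide receptor genes the median log2 fold change was 0.05 (camera adjusted p = 0.899, from 0.708 to 0.949 over the alternatives). The rising alarmin, cytokine, lipid mediator and neuropeptide receptor genes were Ltb4r1, Il18r1, Crlf2, Calcrl and Il18rap. The mean of the whole receptor list was 0.02 and the camera test pointed down.

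Transcription factors of lymphocytes moved in both directions. Irf4, a factor of activated lymphocytes, rose from 43.0 ± 0.256 to 428 ± 105 CPM (log2 fold change 3.32, SE 0.20, adjusted p = 0.000145). Batf, its partner at AP-1 composite sites, rose from 15.0 ± 3.41 to 33.6 ± 2.45 CPM (log2 fold change 1.17, SE 0.19, adjusted p = 0.00572). Batf lost its call without PBS replicate 2 (adjusted p = 0.0752), with 8.49e-08 to 0.0752 over the alternatives. Ikzf2, which encodes Helios, fell from 135 ± 18.2 to 74.6 ± 0.551 CPM (log2 fold change -0.85, SE 0.14, adjusted p = 0.00596). Ikzf2 lost its call without PBS replicate 2 (adjusted p = 0.0835), with 2.48e-06 to 0.0835 over the alternatives. Of 51 measured lymphoid transcription factor genes, 12 rose, 5 fell and 34 did not pass the test, against 14 up and 8 down adjusted over the list alone. Rises of lymphoid transcription factor genes numbered 2, 1, 13 and 12 and falls 2, 1, 5 and 9 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For lymphoid transcription factor genes the median log2 fold change was 0.06 (camera adjusted p = 0.578, from 0.0706 to 0.982 over the alternatives). The falling lymphoid transcription factor genes were Zbtb16, Ikzf2, Bach2, Klf2 and Klf4.

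Smarca4, the gene of Brg1, did not pass the test, at 160.4 ± 12.7 CPM in PBS and 201 ± 9.03 CPM in papain (log2 fold change 0.33, SE 0.14, adjusted p = 0.12). Smarca4 was called with library size only (adjusted p = 0.0482), with 0.0482 to 0.495 over the alternatives. Actb, which also encodes cytoskeletal actin, rose from 525 ± 95.9 to 1240.3 ± 134 CPM (log2 fold change 1.24, SE 0.18, adjusted p = 0.00335). Actb lost its call without PBS replicate 2 (adjusted p = 0.061), with 8.87e-12 to 0.061 over the alternatives. Bcl7a fell from 14.2 ± 1.03 to 7.09 ± 0.226 CPM (adjusted p = 0.0132). Bcl7a lost its call with either PBS replicate left out (log2 fold changes -1.082 to -0.923 over left-out libraries). Of 28 measured SWI/SNF (BAF, PBAF and ncBAF) subunit genes, 4 rose, 3 fell and 21 did not pass the test, against 6 up and 3 down adjusted over the list alone. Rises of SWI/SNF (BAF, PBAF and ncBAF) subunit genes numbered 1, 0, 5 and 5 and falls 0, 0, 1 and 5 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For SWI/SNF (BAF, PBAF and ncBAF) subunit genes the median log2 fold change was -0.03 (camera adjusted p = 0.899, from 0.785 to 0.991 over the alternatives). The rising SWI/SNF subunit genes were Actb, Smarcd2, Brd7 and Actl6a, and the falling ones Bcl7a, Bicra and Bicral. The mean of the whole SWI/SNF list was 0.01 and its camera test pointed down. With scaling by library size only its median was 0.06.

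Energy and lipid metabolism genes were called higher as lists with the preset correlation. Cox5a, a subunit of cytochrome c oxidase, rose from 25.3 ± 1.39 to 56.8 ± 11.4 CPM (log2 fold change 1.17, SE 0.17, adjusted p = 0.0036). Cox5a lost its call with either PBS replicate left out (log2 fold changes 0.949 to 1.347 over left-out libraries). Of 44 measured nuclear-encoded oxidative phosphorylation genes, 18 rose, 0 fell and 26 did not pass the test, against 26 up and 0 down adjusted over the list alone. Rises of nuclear-encoded oxidative phosphorylation genes numbered 0, 2, 10 and 25 and falls 0, 0, 0 and 0 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For nuclear-encoded oxidative phosphorylation genes the median log2 fold change was 0.46 (camera adjusted p = 3.68e-07, from 7.19e-09 to 0.481 over the alternatives, and adjusted p = 0.481 with an estimated correlation). The nuclear-encoded oxidative phosphorylation list lost its call with fry (adjusted p = 0.0797). Fdps, which encodes farnesyl diphosphate synthase, rose from 9.13 ± 0.399 to 22.7 ± 1.92 CPM (log2 fold change 1.31, SE 0.18, adjusted p = 0.00298). Fdps lost its call with either PBS replicate left out (log2 fold changes 1.23 to 1.387 over left-out libraries). Of 25 measured cholesterol biosynthesis genes, 8 rose, 1 fell and 16 did not pass the test, against 13 up and 1 down adjusted over the list alone. Rises of cholesterol biosynthesis genes numbered 1, 1, 10 and 8 and falls 0, 0, 1 and 1 with 1 library left out, in the same order. For cholesterol biosynthesis genes the median log2 fold change was 0.45 (camera adjusted p = 0.00108, from 0.000441 to 0.481 over the alternatives, and adjusted p = 0.481 with an estimated correlation). The cholesterol biosynthesis list lost its call with fry (adjusted p = 0.0523). The falling cholesterol biosynthesis gene was Mvk. Scd2, a fatty acid desaturase, rose from 14.3 ± 1.16 to 46.1 ± 3.62 CPM (log2 fold change 1.69, SE 0.16, adjusted p = 0.000562). Of 33 measured fatty acid uptake, storage and oxidation genes, 10 rose, 1 fell and 22 did not pass the test, against 14 up and 1 down adjusted over the list alone. Rises of fatty acid uptake, storage and oxidation genes numbered 1, 2, 8 and 11 and falls 0, 0, 1 and 1 with 1 library left out, in the same order. For fatty acid uptake, storage and oxidation genes the median log2 fold change was 0.41 (camera adjusted p = 0.000585, from 0.000151 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The fatty acid uptake, storage and oxidation list lost its call with fry (adjusted p = 0.0695). The falling fatty acid uptake, storage and oxidation gene was Acsl1.

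Amino acid metabolism was called higher as a list with the preset correlation, while glycolysis, polyamine and ribosome genes moved in part. The summed CPM of the amino acid list overlapped between groups, at 3546 and 3093 in PBS and 3058 and 3750 in papain. Mthfd2, a mitochondrial enzyme of one-carbon metabolism, rose from 2.58 ± 0.485 to 26.5 ± 2.39 CPM (log2 fold change 3.36, SE 0.23, adjusted p = 0.000166). Psat1, an enzyme of serine synthesis, rose from 21.1 ± 1.20 to 58.7 ± 2.71 CPM (log2 fold change 1.47, SE 0.14, adjusted p = 0.000594). Of 27 measured amino acid transport and one-carbon genes, 10 rose, 0 fell and 17 did not pass the test, against 12 up and 1 down adjusted over the list alone. Rises of amino acid transport and one-carbon genes numbered 3, 3, 13 and 8 and falls 0, 0, 0 and 3 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For amino acid transport and one-carbon genes the median log2 fold change was 0.49 (camera adjusted p = 0.00036, from 5.87e-05 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). Pgk1, an enzyme of lower glycolysis, rose from 101 ± 4.44 to 244 ± 11.6 CPM (log2 fold change 1.27, SE 0.13, adjusted p = 0.000915). Of 24 measured glycolysis genes, 7 rose, 1 fell and 16 did not pass the test, against 8 up and 1 down adjusted over the list alone. Rises of glycolysis genes numbered 2, 2, 6 and 9 and falls 0, 0, 0 and 1 with 1 library left out, in the same order. For glycolysis genes the median log2 fold change was 0.18 (camera adjusted p = 0.0921, from 0.0228 to 0.528 over the alternatives). The glycolysis list was called with limma-voom (adjusted p = 0.0452) and without PBS replicate 1 (adjusted p = 0.0228). The falling glycolysis gene was Pdk1. Ass1, which makes argininosuccinate, rose from 19.2 ± 5.39 to 51.5 ± 0.0803 CPM (log2 fold change 1.42, SE 0.20, adjusted p = 0.0028). Arg1, which encodes arginase, rose from 567 ± 62.0 to 984 ± 183 CPM (log2 fold change 0.80, SE 0.18, adjusted p = 0.0177). Arg1 lost its call with either PBS replicate left out (log2 fold changes 0.58 to 0.977 over left-out libraries). Of 17 measured arginine and polyamine genes, 4 rose, 1 fell and 12 did not pass the test, against 5 up and 3 down adjusted over the list alone. Rises of arginine and polyamine genes numbered 1, 1, 2 and 5 and falls 0, 1, 1 and 3 with 1 library left out, in the same order. For arginine and polyamine genes the median log2 fold change was 0.19 (camera adjusted p = 0.262, from 0.0585 to 0.481 over the alternatives). The rising arginine and polyamine genes were Ass1, Arg1, Asl and Oaz2, and Amd1 fell. Polr1b, a subunit of RNA polymerase I, fell from 34.7 ± 1.32 to 21.1 ± 1.46 CPM (log2 fold change -0.71, SE 0.15, adjusted p = 0.0138). Polr1b lost its call with either PBS replicate left out (log2 fold changes -0.798 to -0.642 over left-out libraries). Of 40 measured MYC target and ribosome biogenesis genes, 4 rose, 6 fell and 30 did not pass the test, against 10 up and 13 down adjusted over the list alone. Rises of MYC target and ribosome biogenesis genes numbered 0, 0, 2 and 2 and falls 0, 1, 5 and 9 with 1 library left out, in the same order. For MYC target and ribosome biogenesis genes the median log2 fold change was -0.16 (camera adjusted p = 0.32, from 0.103 to 0.779 over the alternatives). The rising MYC target and ribosome biogenesis genes were Phb2, Pa2g4, Cad and Pes1.

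Genes of protein secretion, redox control and cell death were called higher as lists with the preset correlation. Summed CPM overlapped between groups for secretion (8259 and 8290 in PBS, 7606 and 9480 in papain). It also overlapped for cell death (2522 and 2426 in PBS, 2252 and 2737 in papain), but not for redox control. Ostc, a subunit of the oligosaccharyltransferase, rose from 19.7 ± 2.50 to 44.3 ± 0.0778 CPM (log2 fold change 1.17, SE 0.15, adjusted p = 0.00235). Ostc lost its call without PBS replicate 1 (adjusted p = 0.0587), with 5.39e-09 to 0.0587 over the alternatives. Of 35 measured unfolded protein response and secretory genes, 18 rose, 0 fell and 17 did not pass the test, against 22 up and 0 down adjusted over the list alone. Rises of unfolded protein response and secretory genes numbered 0, 3, 19 and 15 and falls 0, 0, 0 and 3 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For unfolded protein response and secretory genes the median log2 fold change was 0.52 (camera adjusted p = 1.2e-05, from 2.45e-07 to 0.419 over the alternatives, and adjusted p = 0.419 with an estimated correlation). The unfolded protein response and secretory list lost its call with fry (adjusted p = 0.0523). Txn1, which encodes thioredoxin, rose from 49.3 ± 0.971 to 120.1 ± 4.95 CPM (log2 fold change 1.28, SE 0.13, adjusted p = 0.000731). Of 32 measured redox and antioxidant genes, 12 rose, 0 fell and 20 did not pass the test, against 16 up and 0 down adjusted over the list alone. Rises of redox and antioxidant genes numbered 2, 1, 10 and 12 and falls 0, 0, 0 and 1 with 1 library left out, in the same order. For redox and antioxidant genes the median log2 fold change was 0.53 (camera adjusted p = 8.69e-05, from 6.12e-06 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The redox and antioxidant list lost its call with fry (adjusted p = 0.0523). Bak1, which promotes apoptosis, rose from 14.5 ± 1.98 to 48.7 ± 5.84 CPM (log2 fold change 1.75, SE 0.17, adjusted p = 0.000652). Birc5, an apoptosis inhibitor that also acts in mitosis, rose from 2.88 ± 0.910 to 15.8 ± 1.86 CPM (log2 fold change 2.46, SE 0.28, adjusted p = 0.00132). Of 28 measured BCL-2 family and cell death genes, 8 rose, 1 fell and 19 did not pass the test, against 11 up and 2 down adjusted over the list alone. Rises of BCL-2 family and cell death genes numbered 3, 3, 8 and 11 and falls 0, 0, 0 and 3 with 1 library left out, in the same order. For BCL-2 family and cell death genes the median log2 fold change was 0.38 (camera adjusted p = 0.0472, from 0.0127 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The BCL-2 family and cell death list lost its call with library size only (adjusted p = 0.0534), without papain replicate 2 (adjusted p = 0.103) and with ranks (adjusted p = 0.057). The falling BCL-2 family and cell death gene was Bcl2.

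Immediate early genes, which cells transcribe within minutes of stimulation, were called lower as a list with the preset correlation, but not with an estimated one (adjusted p = 0.481) or with fry. Fos, an AP-1 subunit, fell from 4879.9 ± 272 to 2113 ± 96.1 CPM (log2 fold change -1.21, SE 0.15, adjusted p = 0.00207). Ier5, an immediate early response gene, fell from 1268 ± 101 to 563 ± 24.9 CPM (log2 fold change -1.17, SE 0.15, adjusted p = 0.00216). Of 32 measured immediate early and AP-1 genes, 0 rose, 14 fell and 18 did not pass the test, against 2 up and 15 down adjusted over the list alone. Rises of immediate early and AP-1 genes numbered 0, 0, 3 and 0 and falls 4, 3, 11 and 20 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For immediate early and AP-1 genes the median log2 fold change was -0.51 (camera adjusted p = 8.69e-05, from 6.06e-06 to 0.481 over the alternatives, and adjusted p = 0.481 with an estimated correlation). The immediate early and AP-1 list lost its call with fry (adjusted p = 0.102). Klf3, a lymphocyte repressor, fell from 113 ± 3.82 to 62.0 ± 3.86 CPM (log2 fold change -0.87, SE 0.13, adjusted p = 0.0038). Klf3 lost its call with either PBS replicate left out (log2 fold changes -0.931 to -0.818 over left-out libraries). Btg2, an antiproliferative gene, fell from 874 ± 34.8 to 390.1 ± 94.7 CPM (log2 fold change -1.16, SE 0.19, adjusted p = 0.00528). Btg2 lost its call with either PBS replicate left out (log2 fold changes -1.448 to -0.932 over left-out libraries). Of 24 measured quiescence and naive lymphocyte genes, 2 rose, 8 fell and 14 did not pass the test, against 2 up and 8 down adjusted over the list alone. Rises of quiescence and naive lymphocyte genes numbered 2, 2, 2 and 2 and falls 0, 1, 7 and 8 with 1 library left out, in the same order. For quiescence and naive lymphocyte genes the median log2 fold change was -0.33 (camera adjusted p = 0.0358, from 0.0131 to 0.373 over the alternatives, and adjusted p = 0.373 with an estimated correlation). The quiescence and naive lymphocyte list lost its call without papain replicate 1 (adjusted p = 0.0555). The rising quiescence and naive lymphocyte genes were Slfn2 and Ccr7. Nfkbid, a nuclear inhibitor of kappa B, fell from 1621 ± 168 to 796 ± 2.19 CPM (log2 fold change -1.03, SE 0.15, adjusted p = 0.00377). Nfkbid lost its call without PBS replicate 1 (adjusted p = 0.0697), with 6.78e-11 to 0.0697 over the alternatives. Of 29 measured NF-kappaB pathway genes, 5 rose, 4 fell and 20 did not pass the test, against 7 up and 7 down adjusted over the list alone. Rises of NF-kappaB pathway genes numbered 0, 0, 4 and 4 and falls 0, 1, 4 and 9 with 1 library left out, in the same order. For NF-kappaB pathway genes the median log2 fold change was -0.21 (camera adjusted p = 0.275, from 0.14 to 0.704 over the alternatives). The rising NF-kappaB pathway genes were Bcl2a1d, Cflar, Tnip3, Map3k8 and Nfkbib, and the falling ones Nfkbid, Birc3, Map3k14 and Nfkbiz. The mitochondrial ribosomal RNA mt-Rnr2 and the nuclear RNAs Neat1 and Kcnq1ot1 also fell, with log2 fold changes of -0.83, -0.68 and -1.27. mt-Rnr2 lost its call without PBS replicate 1 (adjusted p = 0.0818) and without PBS replicate 2 (adjusted p = 0.133), with 7.31e-06 to 0.133 over the alternatives. Neat1 lost its call with library size only (adjusted p = 0.0558), without PBS replicate 1 (adjusted p = 0.286), without PBS replicate 2 (adjusted p = 0.144) and without papain replicate 2 (adjusted p = 0.0874), with 0.000489 to 0.286 over the alternatives. Kcnq1ot1 lost its call with the robust fit (adjusted p = 0.0782), without PBS replicate 1 (adjusted p = 0.276) and without PBS replicate 2 (adjusted p = 0.105), with 3.08e-09 to 0.276 over the alternatives.

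Genes for trafficking and adhesion receptors rose in part. Ccr7, a homing receptor, rose from 8.65 ± 1.24 to 27.6 ± 3.84 CPM (log2 fold change 1.68, SE 0.20, adjusted p = 0.0016). Itgb1, the integrin beta 1 chain, rose from 129 ± 16.7 to 301 ± 18.9 CPM (log2 fold change 1.21, SE 0.15, adjusted p = 0.00188). Itgb1 lost its call without PBS replicate 1 (adjusted p = 0.0578), with 7.04e-12 to 0.0578 over the alternatives. Of 31 measured trafficking and adhesion receptor genes, 9 rose, 1 fell and 21 did not pass the test, against 10 up and 1 down adjusted over the list alone. Rises of trafficking and adhesion receptor genes numbered 2, 3, 8 and 9 and falls 0, 0, 1 and 3 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. For trafficking and adhesion receptor genes the median log2 fold change was 0.23 (camera adjusted p = 0.0851, from 0.0121 to 0.481 over the alternatives). The trafficking and adhesion receptor list was called with limma-voom (adjusted p = 0.0358) and without PBS replicate 1 (adjusted p = 0.0121). Its falling gene, Klf2, is a transcription factor. Dendritic cell markers, which include Ccr7, stood at 93.9 and 59.0 CPM in PBS and 168 and 95.3 CPM in papain. Across the 23 lists, camera called 11 higher and 2 lower in papain with a preset correlation. With an estimated correlation 0 were called by camera, where 1 list (G2/M and mitosis) had an unadjusted p under 0.05, and fry called 5 higher and 1 lower.

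**Figure D3:**
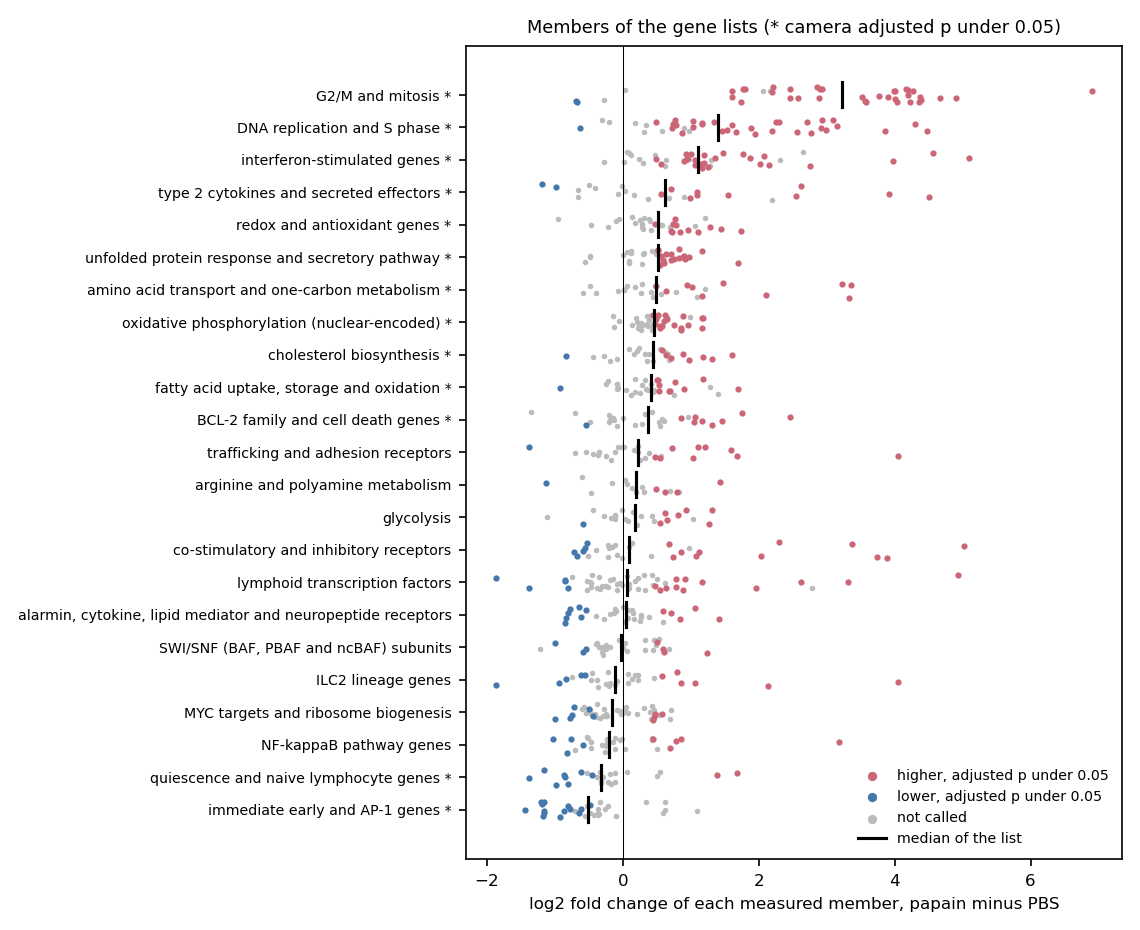
Each point is the log2 fold change (papain minus PBS, x axis) of 1 measured member of the 23 gene lists (y axis), red where called higher, blue where called lower and grey otherwise, and black bars are list medians. Medians run from -0.51 for immediate early genes to 3.23 for G2/M and mitosis, and an asterisk marks a camera adjusted p under 0.05.

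Marker levels of other cell types differed between libraries. Markers of macrophages and monocytes summed to 41.5 and 44.6 CPM in the PBS libraries and 216 and 101 CPM in the papain libraries. Chil3, Ctss, Ccl6 and Lyz2 were the 4 of 8 tested macrophage markers that rose. Lyz2 stood at 39.0 and 7.41 CPM in the papain libraries against a PBS mean of 5.22 ± 0.579 CPM (adjusted p = 0.0466). Lyz2 lost its call with DESeq2 (adjusted p = 0.146), with limma-voom (adjusted p = 0.17), with the robust fit (adjusted p = 0.207), without PBS replicate 1 (adjusted p = 0.259), without PBS replicate 2 (adjusted p = 0.262) and without papain replicate 1 (adjusted p = 0.288), with 3.99e-17 to 0.288 over the alternatives. Ccl6 lost its call with limma-voom (adjusted p = 0.074), without PBS replicate 1 (adjusted p = 0.281), without PBS replicate 2 (adjusted p = 0.105) and without papain replicate 1 (adjusted p = 0.204), with 0.000167 to 0.281 over the alternatives. T cell markers stood at 461 and 488 CPM in PBS and 509.5 and 403 CPM in papain. Of 13 T cell markers, Cd247 rose and Themis fell, with a median of 0.07, a mean of -0.12 and a downward camera test. Cd247 lost its call without PBS replicate 1 (adjusted p = 0.276), without PBS replicate 2 (adjusted p = 0.106) and without papain replicate 1 (adjusted p = 0.108), with 0.00394 to 0.276 over the alternatives. Themis lost its call without PBS replicate 1 (adjusted p = 0.121) and without PBS replicate 2 (adjusted p = 0.154), with 0.00137 to 0.154 over the alternatives. Regulatory T cell markers Ctla4, Nt5e, Tigit and Capg rose and Ikzf2 fell. Mast cell and basophil markers stood at 1249 and 986 CPM in PBS and 703 and 628 CPM in papain. Kit, the most abundant of them, fell from 1088 ± 195 to 610.4 ± 51.4 CPM (log2 fold change -0.83, SE 0.17, adjusted p = 0.0135). Kit lost its call with either PBS replicate left out (log2 fold changes -1.009 to -0.652 over left-out libraries). The fall of the sum was that of Kit, since the median log2 fold change of the 6 tested mast cell and basophil markers was 1.10 and their camera test pointed up (adjusted p = 0.369). Cpa3, a mast cell protease, rose from 18.5 ± 8.90 to 36.7 ± 5.22 CPM (log2 fold change 0.98, SE 0.29, adjusted p = 0.0465). Cpa3 lost its call with the robust fit (adjusted p = 0.0766), without PBS replicate 1 (adjusted p = 0.232) and without papain replicate 2 (adjusted p = 0.0909), with 3.98e-06 to 0.232 over the alternatives. Cd200r3 and Fcer1a did not pass the test, with log2 fold changes of 1.94 and 1.23. Cd200r3 was called with the exact test (adjusted p = 0.0247), with library size only (adjusted p = 0.0442), with no filter (adjusted p = 0.0432) and with the robust fit (adjusted p = 0.0492), with 0.0247 to 0.325 over the alternatives.

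Epithelial markers stood at 89.5 and 35.0 CPM in PBS and 121 and 40.4 CPM in papain. Fibroblast and smooth muscle markers stood at 26.0 and 14.0 CPM in PBS and 70.1 and 10.2 CPM in papain. Rises numbered 4 for macrophage, 1 (Cdh1) for epithelial, 0 for fibroblast and 1 (Ccr7) for dendritic markers. Without papain replicate 2 they numbered 8, 6, 8 and 5, and without papain replicate 1, 2, 0, 0 and 1. Without PBS replicate 1 they numbered 1, 0, 0 and 1, and without PBS replicate 2, 2, 0, 0 and 1. With a replicate-number term they numbered 5, 2, 1 and 5, and with no filter 8, 6, 6 and 5. Cd74, the most abundant dendritic marker, stood at 17.3 ± 9.23 CPM in PBS and 40.9 ± 18.9 CPM in papain (log2 fold change 1.25, SE 0.39, adjusted p = 0.0559). Cd74 was called with the exact test (adjusted p = 0.0127), with library size only (adjusted p = 0.0273), with no filter (adjusted p = 1.4e-09), with a mean CPM of at least 5 (adjusted p = 0.04), with a replicate-number term (adjusted p = 0.000939) and without papain replicate 2 (adjusted p = 0.00795), with 1.4e-09 to 0.314 over the alternatives. Endothelial markers summed to 186 and 112 CPM in PBS and 219.7 and 136 CPM in papain. ILC3 markers summed to 179 and 228 CPM in PBS and 291 and 212 CPM in papain. B and plasma cell markers summed to 111 and 112 CPM in the PBS libraries and 91.7 and 87.1 CPM in the papain libraries, with a downward camera test and an upward fry test. Erythroid and platelet markers summed to 34.2 and 37.1 CPM in the PBS libraries and 37.2 and 9.10 CPM in the papain libraries, with 0 falls, or 4 without papain replicate 1. Neutrophil markers summed to 13.4 and 15.0 CPM in PBS and 19.6 and 6.99 CPM in papain. NK cell and ILC1 markers summed to 9.60 and 5.46 CPM in PBS and 16.7 and 11.2 CPM in papain. Eosinophil markers summed to 1.43 and 0.461 CPM in PBS and 1.57 and 0.964 CPM in papain. No tested marker or quality list passed camera, and the lowest adjusted p was 0.261. Of 6 nuclear-retained and structural RNAs, 2 fell. The table holds 2 mitochondrial transcripts, of which mt-Rnr1 did not pass the test (log2 fold change 0.20, SE 0.16, adjusted p = 0.395).

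**Figure D4:**
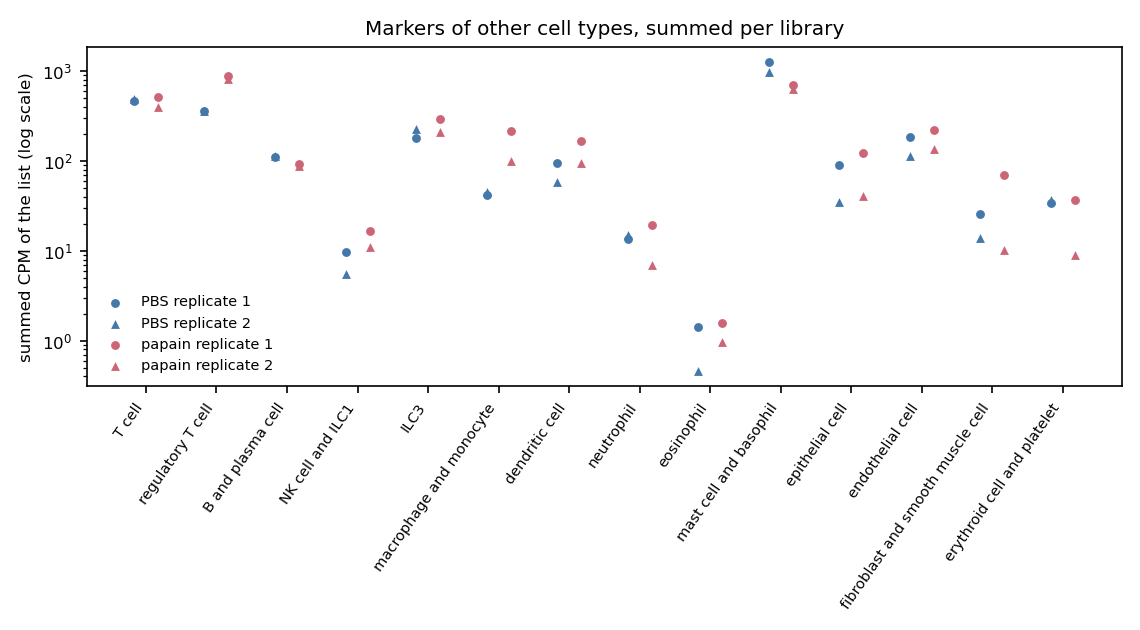
Points are the summed CPM (y axis, log scale) of each marker list (x axis) in each library, with PBS in blue, papain in red, circles for replicate 1 and triangles for replicate 2. Macrophage and monocyte markers lie at 41.5 and 44.6 CPM in the PBS libraries and 216 and 101 CPM in the papain libraries.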

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

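All alternatives were set before the data were examined and none was added. Genes changed numbered 2498 with DESeq2, 2560 with limma-voom, 3277 with the exact test, 2553 with RLE, 2592 with upper quartile and 2760 with library size only, against 2590. They numbered 3570 of 18035 with no filter, 2630 with a mean CPM of at least 5 and 2711 with the robust fit. An adjusted p under 0.01 left 898, and glmTreat against 2-fold left 203 of 958, as stricter thresholds do by construction. With a replicate block, 2913 changed. Deviations of the libraries with equal numbers correlated at 0.258 across genes, and the second principal component parted them the same way, but the labels give these numbers no shared origin. Leaving out 1 library gave 293 to 3123 genes changed, 229 to 1648 higher, 64 to 1475 lower and 292 to 1367 changed at least 2-fold. It gave 10 to 14 lists higher and 1 to 2 lower. With an estimated correlation 0 lists were higher and 0 lower, and fry called 5 higher and 1 lower. Without a PBS library the spread came from the papain pair alone. Its chi-square divided by degrees of freedom was 26.81, against 14.05 for the PBS pair. A call lost there need not mean that the effect rested on the left-out library. The cause of these differences was not tested further. The estimated correlation had 2 residual degrees of freedom, so its lack of calls does not decide whether a list changed. Of 175 named genes with a test, 127 were called, and 59 of them passed without each library in turn. The call was lost for 61 without PBS replicate 1, 56 without PBS replicate 2, 9 without papain replicate 1 and 3 without papain replicate 2. None of the 127 reversed.

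Results that turned were not called, and the cause was not tested. Given are log2 fold changes. S100a8 turned with limma-voom (-1.10) and without papain replicate 1 (-6.08), with -6.08 to 2.02 over left-out libraries. Without PBS replicate 1, Jchain (2.53), Tek (0.68) and Scgb1a1 (0.078) turned. Their ranges over left-out libraries were -3.10 to 2.53, -3.75 to 0.68 and -3.76 to 0.078. Klrk1 turned without PBS replicate 1 (0.032) and without papain replicate 1 (0.19), with -1.13 to 0.19 over left-out libraries. Gata3 turned without PBS replicate 1 (0.088), with -0.26 to 0.088 over left-out libraries. Il17rb turned without PBS replicate 1 (-0.024) and without papain replicate 2 (-0.23), with -0.23 to 0.31 over left-out libraries. Ccr3 turned without PBS replicate 2 (-0.11) and without papain replicate 1 (-0.16), with -0.16 to 1.17 over left-out libraries. S100a9 turned without PBS replicate 2 (1.52) and without papain replicate 2 (0.18), with -3.04 to 1.52 over left-out libraries. Csf3r turned without PBS replicate 2 (0.096) and without papain replicate 2 (0.55), with -2.21 to 0.55 over left-out libraries. Cd79a turned without papain replicate 1 (0.064), with -6.28 to 0.064 over left-out libraries. Without papain replicate 1, Cldn5 (-2.04), Sftpa1 (-0.095), Col1a1 (-0.12), Sparc (-3.25) and Col1a2 (-3.26) turned. Their ranges over left-out libraries were -2.04 to 2.57, -0.095 to 2.65, -0.12 to 5.51, -3.25 to 3.67 and -3.26 to 3.44. Without papain replicate 2, Hba-a1 (0.021) and Hbb-bs (0.37) turned, with -1.72 to 0.021 and -3.62 to 0.37 over left-out libraries. At this depth a direction was not detectable for genes with few counts, such as Ccr3 with 13 and 6 counts in PBS and 20 and 10 in papain. For lists the camera direction turned, and adjusted p-values are given. SWI/SNF (BAF, PBAF and ncBAF) subunits turned with limma-voom (0.949) and with no filter (0.915) and with mean CPM of at least 5 (0.898) and without PBS replicate 2 (0.991) and without papain replicate 1 (0.967), with 0.785 to 0.991 over left-out libraries. ILC2 lineage genes turned without PBS replicate 1 (0.837) and without papain replicate 1 (0.779), with 0.528 to 0.837 over left-out libraries. Lymphoid transcription factors turned without PBS replicate 2 (0.896), with 0.0706 to 0.917 over left-out libraries. Alarmin, cytokine, lipid mediator and neuropeptide receptors turned without papain replicate 1 (0.895), with 0.708 to 0.895 over left-out libraries. The fry test, which asks about change and not about other genes, pointed up for ILC2 lineage genes (0.341), where camera pointed down.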

Other observations

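All 25 gene families looked at, and the tests of heat-shock genes, of the amount of genomic DNA, of small nucleolar RNA genes outside hosts, of T cells and of other lung cell types, were chosen only after the result was seen. Several families of protein turnover and of the cell cortex had medians above 0. Of 45 proteasome subunit genes, 23 rose and 0 fell. Proteasome subunit rises numbered 0, 4, 20 and 21 and falls 0, 0, 0 and 0 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. The proteasome subunit median was 0.46 (camera adjusted p = 7.87e-09, and adjusted p = 0.417 with an estimated correlation). Tap1, the peptide transporter of antigen presentation, rose from 60.8 ± 0.502 to 171 ± 17.9 CPM (log2 fold change 1.49, SE 0.14, adjusted p = 0.000567). Of 23 antigen presentation genes, 10 rose and 0 fell. Antigen presentation rises numbered 1, 3, 8 and 10 and falls 0, 0, 0 and 0 in the same order. The antigen presentation median was 0.44 (camera adjusted p = 0.0048, and adjusted p = 0.547 with an estimated correlation). Anxa2, a membrane-binding annexin, rose from 20.2 ± 1.07 to 169 ± 18.3 CPM (log2 fold change 3.06, SE 0.15, adjusted p = 5.11e-05). Of 9 annexin genes, 6 rose and 0 fell. Annexin rises numbered 1, 1, 6 and 7 and falls 0, 0, 0 and 0 in the same order. The annexin median was 0.76 (camera adjusted p = 0.000361, and adjusted p = 0.417 with an estimated correlation). Lgals3, a galectin, rose from 7.11 ± 0.189 to 39.3 ± 6.55 CPM (log2 fold change 2.47, SE 0.19, adjusted p = 0.000291). Of 46 actin cytoskeleton genes, 16 rose and 2 fell. Actin cytoskeleton rises numbered 4, 3, 17 and 18 and falls 0, 0, 1 and 2 in the same order. The actin cytoskeleton median was 0.51 (camera adjusted p = 2.12e-05, and adjusted p = 0.417 with an estimated correlation). Ctsw, a cathepsin of cytotoxic lymphocytes, rose from 38.4 ± 0.365 to 112 ± 6.64 CPM (log2 fold change 1.54, SE 0.13, adjusted p = 0.000395). Of 13 cathepsin genes, 8 rose and 1 fell. Cathepsin rises numbered 1, 3, 8 and 8 and falls 0, 0, 0 and 0 in the same order. The cathepsin median was 0.78 (camera adjusted p = 0.0111, and adjusted p = 0.417 with an estimated correlation). Of 74 mitochondrial ribosomal protein genes, 14 rose and 0 fell. Mitochondrial ribosomal protein rises numbered 0, 0, 9 and 19 and falls 0, 0, 0 and 0 in the same order. The mitochondrial ribosomal protein median was 0.33 (camera adjusted p = 4.9e-05, and adjusted p = 0.417 with an estimated correlation). Of 7 immunoproteasome genes, 6 rose and 0 fell. Immunoproteasome rises numbered 0, 0, 3 and 5 and falls 0, 0, 0 and 0 in the same order. The immunoproteasome median was 0.51 (camera adjusted p = 0.00255, and adjusted p = 0.467 with an estimated correlation). Macrophages and dendritic cells also express many cathepsin, galectin, annexin, lysosomal and antigen presentation genes. Macrophage and monocyte markers summed to 41.5 and 44.6 CPM in PBS and 216 and 101 CPM in papain. Dendritic cell markers summed to 93.9 and 59.0 CPM in PBS and 168 and 95.3 CPM in papain. Galectin genes numbered 6, of which 3 rose (2, 2, 3 and 3 in the same order) and 0 fell (0, 0, 0 and 0), with a median of 0.52 (camera adjusted p = 0.0493, and adjusted p = 0.519 with an estimated correlation). That call was lost for the galectin genes without PBS replicate 1 (adjusted p = 0.0731) and without PBS replicate 2 (adjusted p = 0.0724) and without papain replicate 1 (adjusted p = 0.0815). Lysosomal membrane and proton pump genes numbered 19, of which 6 rose (1, 1, 3 and 6 in the same order) and 0 fell (0, 0, 0 and 0), with a median of 0.26 (camera adjusted p = 0.0253, and adjusted p = 0.417 with an estimated correlation). That call was lost for the lysosomal membrane and proton pump genes without PBS replicate 1 (adjusted p = 0.0678) and without papain replicate 1 (adjusted p = 0.0546). Translation initiation factor genes numbered 53, of which 7 rose (0, 0, 9 and 8 in the same order) and 2 fell (0, 0, 2 and 3), with a median of 0.25 (camera adjusted p = 0.0293, and adjusted p = 0.56 with an estimated correlation). That call was lost for the translation initiation factor genes without PBS replicate 1 (adjusted p = 0.0678) and without PBS replicate 2 (adjusted p = 0.0724) and without papain replicate 2 (adjusted p = 0.214). Of 79 cytosolic ribosomal protein genes, 1 rose (0, 0, 1 and 5 in the same order) and 0 fell (0, 0, 6 and 0), with a median of -0.006, or 0.080 with library size only (camera adjusted p = 0.977). Their direction turned with 1 library, with a median of -0.19 without papain replicate 1 (adjusted p = 0.00942) and 0.14 without papain replicate 2 (adjusted p = 0.0156).

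Zinc-finger, small nucleolar RNA, SR splicing factor, histone methylation enzyme and GIMAP families had medians below 0, although most of the zinc-finger and small nucleolar RNA genes were not called. Zscan26, a zinc-finger protein, fell from 93.3 ± 0.589 to 40.5 ± 0.668 CPM (log2 fold change -1.20, SE 0.13, adjusted p = 0.000915). Of 334 zinc-finger genes, 7 rose and 69 fell. Zinc-finger rises numbered 0, 0, 6 and 4 and falls 5, 4, 62 and 83 with 1 library left out, in the order PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. The zinc-finger median was -0.44 (camera adjusted p = 3.12e-10, and adjusted p = 0.417 with an estimated correlation). Of 62 small nucleolar RNA genes, 0 rose and 14 fell. Small nucleolar RNA rises numbered 0, 0, 0 and 1 and falls 0, 0, 13 and 14 in the same order. The small nucleolar RNA median was -0.97 (camera adjusted p = 7.53e-11, and adjusted p = 0.417 with an estimated correlation). Of 11 SR splicing factor genes, 0 rose and 6 fell. SR splicing factor rises numbered 0, 0, 0 and 0 and falls 0, 0, 6 and 7 in the same order. The SR splicing factor median was -0.54 (camera adjusted p = 0.0048, and adjusted p = 0.417 with an estimated correlation). Of 35 histone methylation enzyme genes, 0 rose and 6 fell. Histone methylation enzyme rises numbered 0, 0, 0 and 1 and falls 0, 2, 5 and 13 in the same order. The histone methylation enzyme median was -0.33 (camera adjusted p = 0.00279, and adjusted p = 0.514 with an estimated correlation). Gimap3, a GTPase of lymphocytes, fell from 461 ± 44.4 to 173 ± 7.08 CPM (log2 fold change -1.42, SE 0.15, adjusted p = 0.000842). GIMAP genes numbered 8, of which 0 rose (0, 0, 0 and 0 in the same order) and 4 fell (2, 1, 2 and 4), with a median of -0.35 (camera adjusted p = 0.0493, and adjusted p = 0.634 with an estimated correlation). That call was lost for the GIMAP genes without PBS replicate 2 (adjusted p = 0.135) and without papain replicate 1 (adjusted p = 0.331). In all, 15 of the 25 families passed camera with the preset correlation. With an estimated one, which had 2 residual degrees of freedom and so little power, 0 passed. The medians kept their sign with library size only, RLE and upper quartile scaling except for the cytosolic ribosomal proteins, among the families given here.

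The fall of immediate early genes was weighed against 2 technical explanations, the first of them written after the result was seen. A weaker response to tissue dissociation, which induces these genes together with heat-shock genes, is a candidate in the papain libraries. The median log2 fold change of 12 heat-shock genes was -0.224, higher by 0.307 (SE over genes 0.286) than that of the 29 other immediate early genes. The test therefore does not separate a weaker response from a change in the cells before dissociation. That heat-shock median turned with single libraries, at 0.459, -0.583, -0.340 and 0.006 without PBS replicate 1, PBS replicate 2, papain replicate 1 and papain replicate 2. A trend in transcript length or GC content is not enough. The immediate early median stayed at -0.392 (SE over genes 0.102) after it was removed, against -0.509 before. Papain exposure stays open as a biological explanation.

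Of the small nucleolar RNA and zinc-finger genes, 14 of 62 and 69 of 334 fell, and neither family was called with an estimated correlation (adjusted p = 0.417 for both). Removing the trend in length and GC content left the zinc-finger median at -0.464 (SE over genes 0.025), against -0.438 before. This SE does not measure the spread between libraries. With 1 library left out, the median before removal ran from -0.53 to -0.357. For genomic DNA in the PBS libraries, the test written first was met, since olfactory and vomeronasal receptor genes had a papain to PBS ratio of 0.513 (95% counting interval 0.458 to 0.575). A test of the amount, written after that ratio was seen, spoke against it, since DNA at the density on those receptor genes supplied at most 0.113% of either fall. Small nucleolar RNA genes fell more than their 43 host genes, by a median of -0.73 (SE 0.102 from resampling host genes), which met the test written first. But any cause that lowers them would give this, and only 1 tested gene lies outside a host. A larger share of unspliced host RNA in the PBS libraries therefore cannot be told apart from other causes, papain exposure included. RNA was selected with oligo(dT) beads, and 59 of these genes lie inside 1 host gene each. Their counts can hold host RNA and need not measure the level of mature small nucleolar RNA.

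Of 10 regulatory T cell markers, 4 (Ctla4 included) rose and 1 fell (camera adjusted p = 0.261). Many cell-cycle genes rose, and both tests were written after this was seen. T cells in the papain libraries are not enough, since the summed CPM of Cd3d, Cd3e, Trac, Cd4, Cd5 and Cd6 changed by -3.44 while Ctla4 rose by 109.1 CPM. For RNA of other lung cells, the excess of cell-cycle genes over PBS was 1.09 times as high in papain replicate 1 as in papain replicate 2, against 2.97 for the excess of macrophage markers. Epithelial and fibroblast markers had no excess over the PBS mean in papain replicate 2, and the ratios of summed CPM were 2.13, 3 and 6.84 for macrophage, epithelial and fibroblast markers. Papain exposure stays open as an explanation, and a shift of ILC2 subsets within the gate was not tested.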
